A study of Triticum aestivum with 24 samples.

How the data were processed

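Leaf messenger RNA of winter bread wheat (Triticum aestivum, cultivar Alana) was measured by sequencing in 24 libraries, 3 biological replicates in each of 8 groups. The groups crossed drought, elevated temperature and elevated CO2, each present or absent, so that the design was a full factorial. Per the labels, RNA was taken from leaves 3 and 4 of the main tiller at growth stage 61, extracted with a plant RNA column kit with DNase treatment on the column, enriched for poly-A RNA and sequenced as paired ends.

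The deposited values were FPKM, fragments scaled to transcript length and to the number of mapped fragments, made by the authors before deposit for 105200 genes in each of the 24 libraries. Trim Galore 0.4.1, HISAT2, Cuffdiff and DESeq2 are named, per the submitters' processing notes, with no role or order. The genome build, the annotation and any scaling between libraries are not given in the sources used here. Counts were not analysed here, so the absolute depth of each library was unknown and no counting interval was computed. Steps between the low values (under 0.3 FPKM) gave the value of 1 fragment, which combines depth with any scaling of the column. Relative to control replicate 1, it ranged from 0.884 to 1.152 over the 24 libraries. It was read from the most common ratio, held by 11% to 13.7% of the low genes. Ratios far from 1 were left out first, so a large difference could not appear. An FPKM of exactly 0 can be a failed estimate, so such genes are described as listed at 0.

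The columns were of 2 kinds. The 6 temperature+drought and CO2+drought columns were written to 9 decimals, and the other 18 to more. Their median-ratio factors, the median over genes of each library's ratio to the geometric mean library, were 0.8689 to 0.8968 in the 6 and 1.037 to 1.066 in the 18. The median factor of the 2 sets thus differed by 0.242 on the log2 scale, a fold of 1.18. The difference falls wholly between groups, so no fit with the set as a term could separate it from those groups. Counts of called genes are therefore given for the values as deposited and again after each library was divided by its factor, called rescaled below. Rescaling assumes that the typical gene does not change between groups.

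Genes with at least 1 FPKM in at least 3 libraries were tested, which left 45359 genes. Values were transformed as log2(FPKM + 1), and log2 changes on this scale understate the change of low genes. A model with 1 coefficient per group was fitted to all 24 libraries with limma 3.58.1 in R 4.3.3, with a mean-variance trend. P-values were adjusted by Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. Tests were two-sided. The contrasts fixed before the data were examined were the 7 treated groups against control, CO2 added to drought, to temperature and to both, and the 4 interactions of the factorial. The comparison of CO2+temperature+drought with CO2+temperature, the temperature by CO2 interaction without drought, and the difference between the drought effects under CO2+temperature and alone were added after the data were seen. In simulated data for drought against control with 45359 genes, 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. They were drawn from genes with a mean over 2 on the log2(FPKM + 1) scale. Noise was normal, with 1 SD per gene for all groups. The test recovered 56.7%, 89.6% and 97% of them, in that order, and called 6 unchanged genes. These shares do not carry over to lower genes or to groups of unlike spread.

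The files pair the gene identifiers with no names. Of the 105200 identifiers, 0 matched the reference gene table (IWGSC CS RefSeq v2.1), so the 31 gene lists fixed before the data were examined held 0 matched genes and no list was tested. Genes are therefore given by identifier, whose letters and digits after the species prefix name the chromosome and subgenome. For each contrast the rule named at most 2 genes that rose and 2 that fell: those with the largest change among called genes with a mean of at least 5 FPKM in the higher group. For contrasts of 2 groups, the 3 libraries of each group also had to not overlap, which chance gives for 10% of genes. Wheat carries near-identical gene copies on its 3 subgenomes, and how the authors' counting divided fragments among them is not given in the sources used here, so levels of single copies are uncertain.

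Alternatives were a pseudocount of 0.1, no filter on low values, rescaled libraries, library quality weights, a fit to only the libraries compared, the replicate number as a block, and leaving out each library in turn. A fit to only the 18 libraries of the larger set, a fit without drought replicate 2 and CO2+temperature replicate 1, and a fit without the genes present in control libraries alone were added after the data were seen. For each interaction, the term was also left out of the model and the residuals of the 24 libraries, which still held it, were permuted. The model was then refitted, in 100 orders with the real one included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.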

Results

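Transcript levels in wheat leaves were compared between plants grown without treatment and plants grown under drought (soil water content of 25 ± 5%), elevated temperature (up to 31 °C), elevated CO2 (700 ppm), and every combination of these. Each of the 8 groups had 3 biological replicates. Between 61757 and 64248 of the 105200 genes lay above 0 FPKM in each library, and 28466 genes were listed at 0 in every library. Within groups, the correlation of log2(FPKM + 1) between replicates ranged from 0.93 to 0.993 across genes, which are not independent replicates. The spread between replicates was smallest in the CO2 group (root mean square SD of 0.141 on the log2 scale, n = 3). It was largest in the CO2+temperature+drought group (0.305, n = 3) and the temperature+drought group (0.291, n = 3).

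The 6 temperature+drought and CO2+drought libraries had median-ratio factors of at most 0.8968, against at least 1.037 in the other 18. Contrasts with these groups are therefore given as deposited and rescaled.

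**Figure D1:**
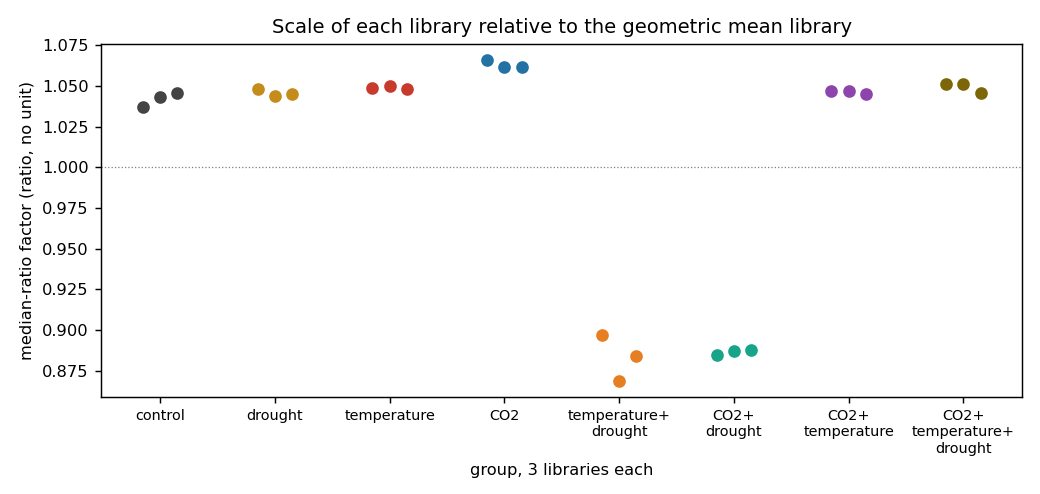
Median-ratio factor (vertical axis, a ratio without unit) of each library by group, 3 points per group, where 1 is the geometric mean library. The 6 temperature+drought and CO2+drought libraries sit between 0.8689 and 0.8968, and the other 18 between 1.037 and 1.066.

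After rescaling, the first 3 principal components held 31.4%, 16.2% and 15.9% of the variance. Control, drought and temperature libraries had negative scores on the first component, and temperature+drought and CO2+drought libraries had positive ones. Drought libraries lay beside the controls. The CO2+drought replicates spread from 25.42 to 72.83 on this component, and the CO2+temperature+drought replicates from -1.518 to 41.91. In the deposited values, drought, temperature and CO2 accounted for 14.4%, 14.7% and 14.3% of the variance over genes, and the temperature by CO2 interaction for 13.7%. Differences between replicates accounted for 27.7%.

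**Figure D2:**
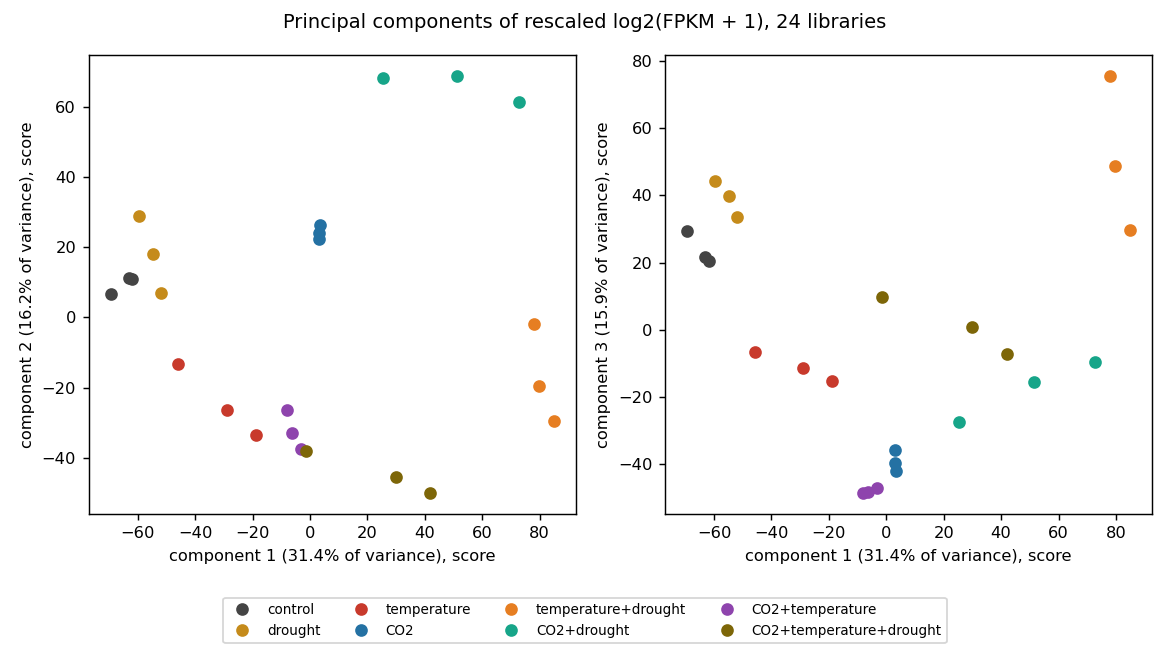
Scores of the 24 libraries on components 1 and 2 (left) and 1 and 3 (right) of rescaled log2(FPKM + 1), with 1 point per library and colours for the 8 groups. Drought lies near control, and the temperature+drought libraries have the highest scores on component 1, from 78.09 to 85.

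Drought alone changed the fewest genes of the 7 treated groups. TraesCS2A02G104600 rose from 0.81 ± 0.107 FPKM (SD, n = 3) in control to 13.1 ± 10.7 FPKM (SD, n = 3), a log2 change of 2.62 (SE 0.42; limma, Benjamini-Hochberg adjusted p = 0.0013). TraesCS7A02G176400 rose from 0.369 ± 0.0796 to 11.2 ± 10.8 FPKM (log2 change 2.59, SE 0.53; limma, Benjamini-Hochberg adjusted p = 0.011), a call lost without control replicate 1, drought replicate 1 or drought replicate 2. TraesCS3B02G010200 fell from 122 ± 2.68 to 0.0122 ± 0.0145 FPKM, a log2 change of -6.92 (SE 0.06; limma, Benjamini-Hochberg adjusted p = 1.8e-24). TraesCS1B02G401400 fell from 39.3 ± 17.1 to 0.255 ± 0.153 FPKM (log2 change -4.90). Both genes that fell were among 96 genes present in the control libraries alone, called control-only below, so the same difference enters every contrast with control. Of the 45359 genes tested, 488 were higher and 378 lower, 866 in all, and 109 and 132 of these changed by at least 1 on the log2 scale. On rescaled values, where 367 genes fell, falls were over-represented on the B subgenome (1.14% of tested genes, odds ratio 1.77; Fisher's exact test, Benjamini-Hochberg adjusted p = 4.4e-06) and under-represented on the D subgenome (0.455%, odds ratio 0.457, adjusted p = 4.0e-08). Of the 102 such tests over 17 contrasts, 3 subgenomes and both directions, no other passed an adjusted p of 0.05. Without the control-only genes, a test chosen after the data were seen, the odds ratios were 1.7 on B (adjusted p = 1.3e-05 over 3 tests) and 0.506 on D (adjusted p = 2e-06). The control-only genes were themselves under-represented on D (16 of 96, odds ratio 0.391, Fisher's exact p = 0.00022). Their rule leaves in any gene only partly higher in control. Leaving them out thus cannot separate an effect of drought from a difference of the control plants. Fisher's exact test takes genes as independent, but these genes come from the same libraries and can move together. Its p-values here can thus be too small. Of the 132 larger falls, 72 were of genes present in the control libraries alone and lower in each of the 7 treated groups. The total was 392 without control replicate 1 (160 higher, 232 lower), 562 without control replicate 2, 416 without drought replicate 1 (176 higher, 240 lower) and 420 without drought replicate 2 (184 higher, 236 lower). Falls also outnumbered rises without control replicate 3 (327 and 263) and with no filter (720 and 528), and the total was 1652 in a fit to only the 6 libraries compared and 5792 with library quality weights.

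Elevated temperature alone changed 7525 genes, of which 4099 were higher and 3426 lower. Larger changes were mostly falls, with 971 genes lower and 198 higher by at least 1 on the log2 scale. TraesCS4D02G134900 rose from 8.46 ± 0.975 to 424 ± 273 FPKM (SD, n = 3 each; log2 change 5.20, SE 0.48; limma, Benjamini-Hochberg adjusted p = 2.4e-07). TraesCS4B02G140200, on the B subgenome, rose from 2.94 ± 0.377 to 97.4 ± 60.9 FPKM (log2 change 4.37). TraesCS5D02G180900 fell from 62.9 ± 4.98 to 0.79 ± 0.804 FPKM (log2 change -5.26, SE 0.26; limma, Benjamini-Hochberg adjusted p = 1.1e-11). The control-only gene TraesCS3B02G010200 fell by 6.91 on the log2 scale. With library quality weights the test called 19020 genes.

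Elevated CO2 alone changed 16011 genes, with 9004 higher and 7007 lower. TraesCS6D02G026500 rose from 1.16 ± 0.0153 to 93.5 ± 3.21 FPKM (SD, n = 3 each; log2 change 5.45, SE 0.44; limma, Benjamini-Hochberg adjusted p = 1.7e-08), and TraesCS5A02G219300 from 2.64 ± 0.938 to 67 ± 23.6 FPKM (log2 change 4.19). The gene TraesCS5D02G180900 fell by 4.69 on the log2 scale, to 1.51 ± 0.472 FPKM (limma, Benjamini-Hochberg adjusted p = 6.0e-11), and the control-only TraesCS3B02G010200 fell by 6.90. Changes of at least 1 on the log2 scale were met by 1171 genes that rose and 1187 that fell.

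**Figure D3:**
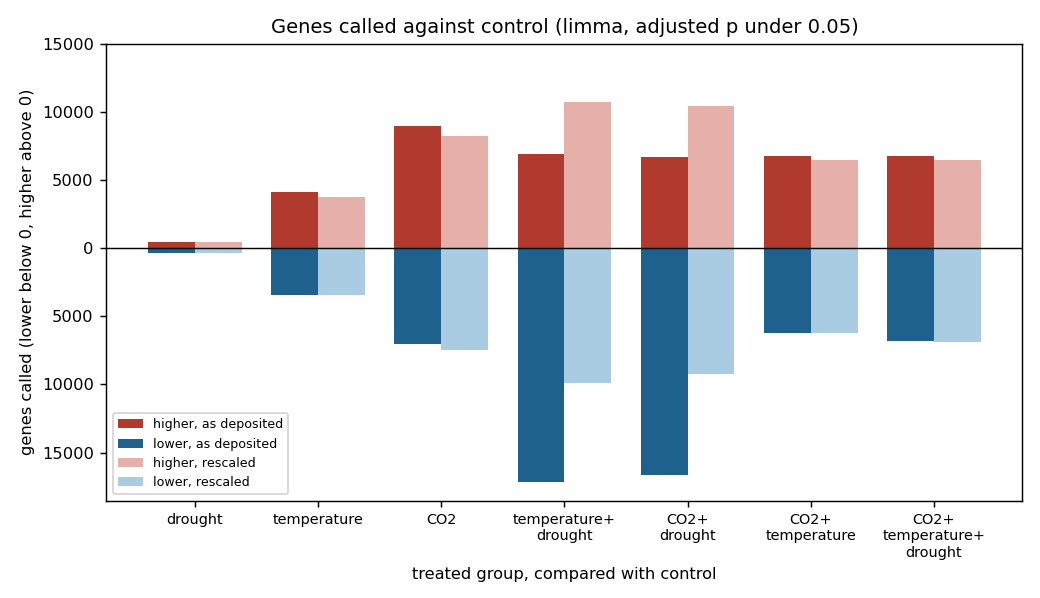
Genes called against control in each treated group (limma, Benjamini-Hochberg adjusted p under 0.05; n = 3 libraries per group), with rises above 0 and falls below 0, for FPKM as deposited (dark) and rescaled (light). Falls in temperature+drought drop from 17132 to 9877 on rescaling and rises go from 6914 to 10768.

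Temperature combined with drought changed 24046 genes as deposited and 20645 rescaled. TraesCS5D02G042300 was listed at 0 in the 3 controls and stood at 236, 64.3 and 102 FPKM in the 3 treated libraries (limma, Benjamini-Hochberg adjusted p = 6.6e-06). TraesCS3B02G336300 was likewise listed at 0 in the controls and stood at 127, 63.4 and 79.8 FPKM. TraesCS7A02G034500 fell from 299 ± 8.56 to 1.42 ± 1.1 FPKM (SD, n = 3 each; log2 change -7.05, SE 0.57; limma, Benjamini-Hochberg adjusted p = 6.2e-09), and the control-only TraesCS3B02G010200 fell by 6.94. In this group 54 genes listed at 0 in the 3 controls reached at least 1 FPKM in all 3 libraries, against 0 genes in each single treatment, 5 in CO2+drought, 17 in CO2+temperature and 19 in CO2+temperature+drought. In the other direction, from at least 1 FPKM in the controls to 0, there were 64 genes here, of which 43 were control-only. The other groups had 43 such genes in drought and 43 in temperature, all control-only, and 46 in CO2, 42 of them control-only. CO2+drought had 51, CO2+temperature 49 and CO2+temperature+drought 53, of which 43, 44 and 45 were control-only. The direction of the calls depended on rescaling: 6914 genes were higher and 17132 lower as deposited (28.8% higher), and 10768 higher and 9877 lower rescaled (52.2% higher). The median over all genes lay at -0.19 as deposited and -0.0078 rescaled, on the log2 scale.

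CO2 combined with drought changed 23383 genes as deposited and 19662 rescaled. TraesCS5D02G042300 stood at 273, 13.3 and 128 FPKM, against 0 in the controls (limma, Benjamini-Hochberg adjusted p = 2.1e-05). TraesCS6A02G137400 rose from 0.37 ± 0.281 to 90.9 ± 58.1 FPKM (SD, n = 3 each; log2 change 5.85, SE 0.42; limma, Benjamini-Hochberg adjusted p = 1.6e-09). TraesCS5D02G180900 fell to 0.176 ± 0.0749 FPKM (log2 change -5.76), and the control-only TraesCS3B02G010200 was listed at 0 in all 3 libraries. As deposited, 6729 genes were higher and 16654 lower (28.8% higher), and rescaled, 10460 were higher and 9202 lower (53.2% higher).

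CO2 combined with temperature changed 12971 genes, with 6764 higher and 6207 lower. TraesCS4A02G177600 rose from 1.17 ± 0.171 to 705 ± 182 FPKM (SD, n = 3 each; log2 change 8.31, SE 0.57; limma, Benjamini-Hochberg adjusted p = 1.0e-09). TraesCS5B02G257000 rose from 0.0812 ± 0.0771 to 300 ± 69.7 FPKM (log2 change 8.10, SE 0.26; limma, Benjamini-Hochberg adjusted p = 7.2e-15). TraesCS5D02G180900 fell by 5.47 and the control-only TraesCS3B02G010200 by 6.89 on the log2 scale. Larger changes were 1008 rises and 1540 falls of at least 1. The count was 20967 with library quality weights.

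All 3 treatments together changed 13610 genes against control, with 6783 higher and 6827 lower. TraesCS4A02G177600 reached 580 ± 360 FPKM (SD, n = 3; log2 change 7.79, SE 0.57; limma, Benjamini-Hochberg adjusted p = 2.9e-09) and TraesCS4D02G134900 reached 1750 ± 682 FPKM (log2 change 7.45). TraesCS5D02G180900 fell by 5.86 and the control-only TraesCS3B02G010200 by 6.93 on the log2 scale. Changes of at least 1 on this scale comprised 1428 rises and 1722 falls. With library quality weights 28308 genes were called.

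**Figure D4:**
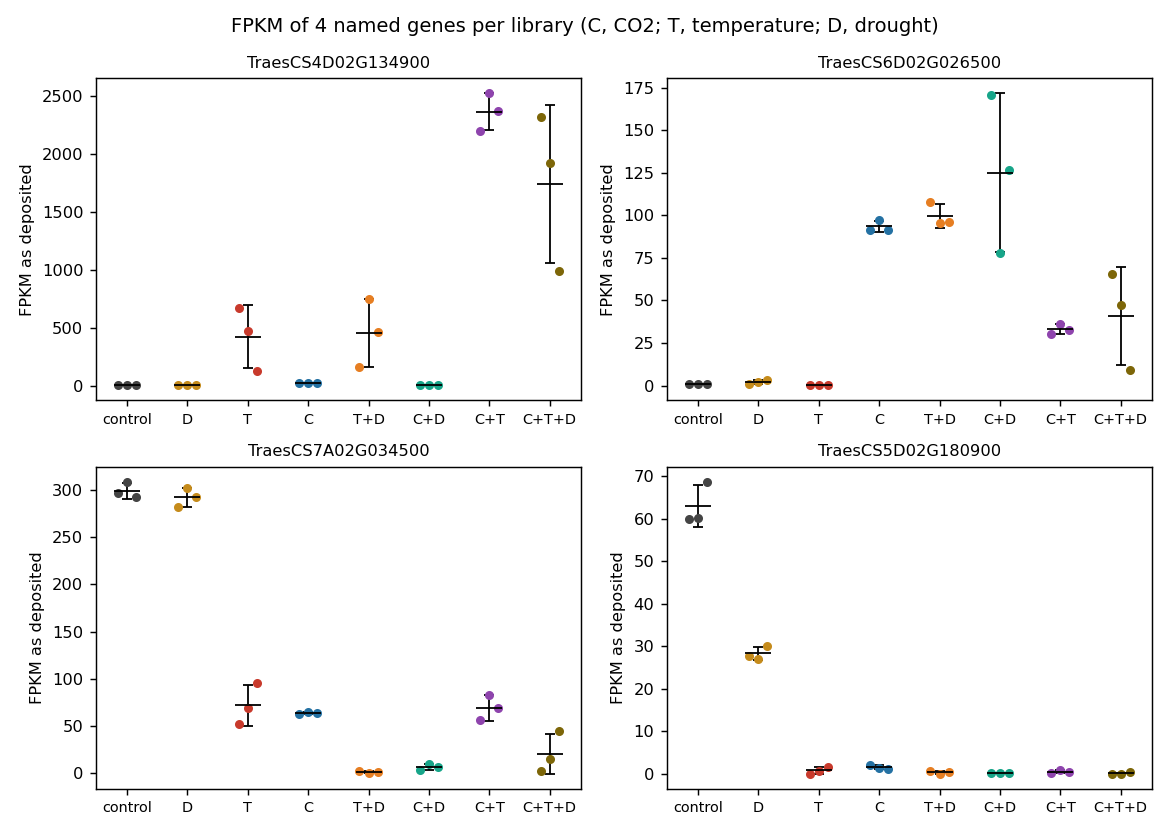
FPKM as deposited (vertical axis, linear) of 4 named genes in each library, with the mean and SD of the 3 libraries of each group. TraesCS4D02G134900 has overlapping levels in CO2+temperature (2370 ± 161 FPKM) and all 3 treatments (1750 ± 682), TraesCS6D02G026500 is at 93.5 ± 3.21 FPKM under CO2 alone, TraesCS7A02G034500 overlaps between control (299 ± 8.56) and drought (292 ± 9.92), and TraesCS5D02G180900 is higher in control (62.9 ± 4.98) than in any other library.

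The effect of CO2 was next measured in plants that already had another treatment. Added to drought, CO2 changed 22284 genes as deposited, 5740 higher and 16544 lower (25.8% higher), and 18466 rescaled, 9437 higher and 9029 lower (51.1% higher). TraesCS5D02G042300, listed at 0 in the 3 drought libraries, and TraesCS7D02G428800 had the largest rises, the latter from 0.786 ± 0.317 to 115 ± 88.5 FPKM (SD, n = 3 each; log2 change 5.58; limma, Benjamini-Hochberg adjusted p = 2.8e-05). TraesCS5B02G407200 fell from 86.3 ± 1.43 to 0.733 ± 0.154 FPKM (log2 change -5.66; limma, Benjamini-Hochberg adjusted p = 5.9e-11), and TraesCS7A02G034500 fell from 292 ± 9.92 to 6.38 ± 3.15 FPKM. With library quality weights the count was 33608.

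Added to elevated temperature, CO2 changed 6216 genes, 3263 higher and 2953 lower. TraesCS5A02G257700 rose from 0.385 ± 0.261 to 123 ± 37.8 FPKM (SD, n = 3 each; log2 change 6.45; limma, Benjamini-Hochberg adjusted p = 1.4e-11), and TraesCS5B02G257000 rose from 3.16 ± 0.949 FPKM by 6.18 on the log2 scale. TraesCS7A02G235100 fell from 53.9 ± 3.37 to 0.863 ± 0.27 FPKM (log2 change -4.89; limma, Benjamini-Hochberg adjusted p = 1.5e-13), and TraesCS5B02G407200 fell from 62.1 ± 36.6 to 1.63 ± 0.29 FPKM. The count was 18215 with library quality weights.

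Added to temperature and drought together, CO2 changed 20950 genes as deposited, 15934 higher and 5016 lower (76.1% higher). Rescaled, 15418 genes changed, 6893 higher and 8525 lower (44.7% higher). TraesCS1B02G449300 rose from 0.679 ± 0.437 to 38.2 ± 15.6 FPKM (SD, n = 3 each). Its log2 change was 4.50 (limma, Benjamini-Hochberg adjusted p = 4.9e-11), and it stayed below its control level of 89.9 ± 19.9 FPKM. TraesCS2A02G527100 rose from 0.526 ± 0.128 to 26.3 ± 8.67 FPKM. TraesCS1B02G317500 fell from 51.6 ± 20.5 to 0.253 ± 0.24 FPKM (log2 change -5.34), and TraesCS2B02G079200 from 239 ± 56 to 6.42 ± 3.59 FPKM (log2 change -5.10; limma, Benjamini-Hochberg adjusted p = 2.2e-07). The count was 8291 in a fit to only the 6 libraries compared and 42899 with library quality weights.

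**Figure D5:**
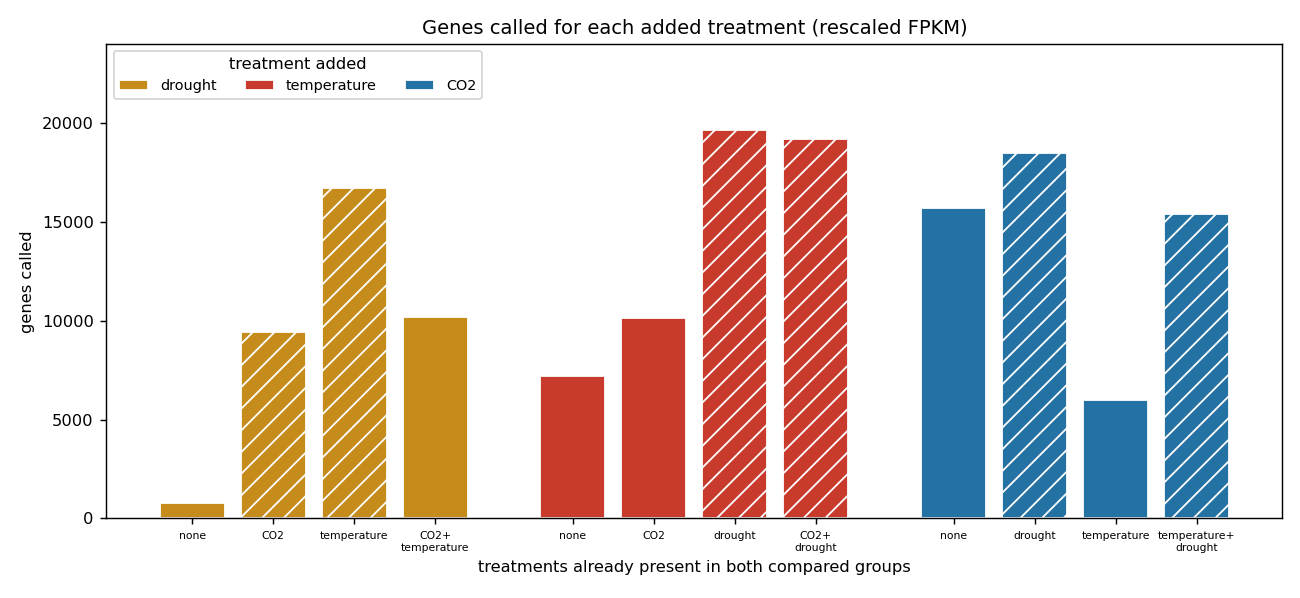
Genes called (vertical axis) when drought, temperature or CO2 was added to each background (horizontal axis), rescaled FPKM, n = 3 libraries per group; hatched bars involve the temperature+drought or CO2+drought libraries. Drought called 801 genes on no background and 10177 on CO2+temperature.

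The interactions of the factorial tested whether the effect of a treatment differed with another, averaged over the remaining treatment. Drought and temperature interacted in 9152 genes (4639 positive, 4513 negative). TraesCS6D02G358900 stood at 39.5 ± 4.66 FPKM in control, 361 ± 388 under temperature and 0.675 ± 0.693 under temperature+drought (SD, n = 3 each; interaction -6.27, SE 0.80; limma, Benjamini-Hochberg adjusted p = 1.9e-05). TraesCS2D02G431500 reached 25.6 ± 8.64 FPKM under temperature+drought, against 0.332 ± 0.147 under drought and 0.431 ± 0.402 under temperature (interaction 3.88). Drought and CO2 interacted in 6313 genes (2181 positive, 4132 negative), among them TraesCS6D02G199100 (interaction -3.15, limma, Benjamini-Hochberg adjusted p = 0.00071). Its mean fell with CO2 from 44.6 ± 0.144 to 2.58 ± 0.9 FPKM under drought and from 15.7 ± 4.72 to 5.28 ± 0.675 without. With temperature added, it fell from 231 ± 27.5 to 16.4 ± 17.5 FPKM under drought and from 5.36 ± 1.92 to 3.74 ± 1.55 without. The counts of genes for drought by temperature and drought by CO2 were 9270 and 6233 rescaled, and 25784 and 21840 with library quality weights.

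Temperature and CO2 interacted in 24047 genes as deposited (17127 positive, 71.2%) and 20284 rescaled (9824 positive, 48.4%). TraesCS5A02G219300 stood at 67 ± 23.6 FPKM under CO2 and 3.52 ± 0.438 under CO2+temperature (SD, n = 3 each). It stood at 2.64 ± 0.938 FPKM in control and 3.79 ± 1.25 under temperature. Its interaction was -4.96 (SE 0.43, limma, Benjamini-Hochberg adjusted p = 3.3e-08). TraesCS7A02G034500 had an interaction of 5.07 in the other direction. Without the drought groups, which hold the 6 libraries with low factors, the temperature by CO2 interaction was called in 7888 genes (3061 positive, 4827 negative). TraesCS5A02G257700 was the gene with the second largest positive value there, at 0.122 ± 0.0802 FPKM under CO2, 0.385 ± 0.261 under temperature and 123 ± 37.8 under both (interaction 6.33; limma, Benjamini-Hochberg adjusted p = 5.5e-09). With library quality weights this count was 19591.

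The interaction of all 3 treatments was called in 17272 genes as deposited (14304 positive, 82.8%) and 9706 rescaled (4190 positive, 43.2%). TraesCS1B02G449300 and TraesCS1B02G449400, neighbours by identifier, had the largest positive values, 6.60 (SE 0.44) and 6.27 (SE 0.46; limma, Benjamini-Hochberg adjusted p = 4.1e-09 and 1.7e-08). TraesCS1B02G449400 stood at 1.95 ± 0.928 FPKM under temperature+drought and 5.22 ± 1.17 under CO2+drought (SD, n = 3 each). These are the groups with low median-ratio factors. Under all 3 treatments it stood at 37.3 ± 12.5 FPKM, below its control level of 68.1 ± 11.7. In the other groups it lay at 52.7 ± 6.34 (drought), 59.5 ± 7.33 (temperature), 54.4 ± 8.71 (CO2) and 70 ± 4.07 FPKM (CO2+temperature). The count was 30807 with library quality weights.

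Drought added to CO2 and temperature changed 10439 genes, 4906 higher and 5533 lower. TraesCS7D02G428800 rose from 0.494 ± 0.295 to 42.9 ± 37.3 FPKM (SD, n = 3 each; log2 change 3.90; limma, Benjamini-Hochberg adjusted p = 0.0023), and TraesCS6B02G412100 fell from 128 ± 42.6 to 0.334 ± 0.0651 FPKM (log2 change -6.54; limma, Benjamini-Hochberg adjusted p = 9.8e-06). The drought effect under CO2 and temperature differed from the drought effect alone in 5844 genes, 2314 positive and 3530 negative. The first count was 6872 in a fit to only the 6 libraries compared. With library quality weights the counts were 27658 and 18904.

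Effects of each treatment were compared across backgrounds on rescaled values, between contrasts that share no library. The CO2 effects without and with drought correlated at r = 0.67 across genes (Spearman's rho 0.622), and 9193 of the 9540 genes called in both had the same direction. Without and with temperature, r was 0.364, and 2962 of 3341 genes had the same direction. Between no background and temperature+drought, r was -0.114, and 1994 of 6575 genes (30.3%) had the same direction. Independent lists of the same sizes would share 3200, 1043 and 2656 genes in the same direction in these 3 pairs, in the order given. The 3 other pairs of CO2 effects had r of 0.341 (temperature and drought backgrounds), 0.174 (temperature and temperature+drought) and -0.271 (drought and temperature+drought). The temperature effects without and with drought correlated at r = 0.448 (4194 of 4664 genes in the same direction), the highest of their 6 pairs. Under CO2 without and with drought r was 0.394 (5089 of 6007), and without and with CO2 it was 0.225 (1594 of 2310). It was 0.0583 between no background and CO2+drought, 0.0338 between CO2 and drought, and -0.0496 between drought and CO2+drought, where 3957 of 9751 genes (40.6%) had the same direction. Independent lists would share 1566, 805, 2158 and 4155 genes for temperature without and with drought, without and with CO2, under CO2 without and with drought, and between drought and CO2+drought. For drought without and with CO2+temperature r was 0.199, and 158 of 249 genes had the same direction, against 89.33 for independent lists. The other 5 pairs of drought effects lay between 0.168 and 0.436. Noise between replicates lowers r, most where effects are small, as for drought alone. With the noise of the effect of drought alone allowed for, slopes on it were 0.527 with CO2+temperature, 0.885 with temperature and 0.501 with CO2. A low r is thus not by itself a sign that drought acted differently between backgrounds. In 3 of the 18 pairs both contrasts held temperature+drought or CO2+drought libraries, so a difference between those 6 libraries and the rest that remained after rescaling entered both. It entered with opposite signs for CO2 between drought and temperature+drought (r = -0.271) and for temperature between drought and CO2+drought (r = -0.0496), and with the same sign for drought between temperature and CO2 (r = 0.436). Genes are not independent replicates, so no p-value is given for these 18 correlations.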

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

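The tests of splits and of the scale of the 6 libraries were written after the results they bear on were seen, as were the contrast without drought and the contrast of drought effects. The permutations of residuals were added after the counts of genes, but before their own outcome was seen. Each result here was picked out because the effect of a treatment differed between backgrounds by a test of the interaction itself (limma, adjusted by Benjamini and Hochberg). The drought by temperature interaction was called in 9152 genes. It was 3.88 for TraesCS2D02G431500, 3.82 for TraesCS5D02G299400, -6.27 for TraesCS6D02G358900 and -5.77 for TraesCS6B02G412100. In 100 different splits of the 24 libraries into 8 groups of 3, the real one included, only the real split (1 of 100) called as many genes, and the highest other called 921. Such splits also break up the effects of the single treatments, which raises the spread within groups and lowers the calls. They therefore do not test the interaction, and a low count in them was likely from the start. Next, the interaction was left out of the model, all other group differences were kept and the residuals were permuted. In this test 1 of 100 orders, the real one, called as many genes, and the highest other called 1. These residuals still held the interaction, scattered over the libraries. As in the splits, this raises the spread within groups and can lower the calls, here and in every permutation below. The drought by CO2 interaction was called in 6313 genes, also in 1 of 100 splits, with 3183 in the highest other, and in 1 of 100 permutations of residuals, with 2383 in the highest other. It was 3.43 for TraesCS3B02G010200, 2.36 for TraesCS1B02G401400, -3.29 for TraesCS6D02G026500 and -3.15 for TraesCS6D02G199100. The first 2 genes are control-only, so their values come from the control libraries.

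For temperature by CO2, 24047 genes were called as deposited, in 1 of 100 splits, with 1112 in the highest other, and in 1 of 100 permutations, with 15680 in the highest other; neither separates it from the shift of the 6 libraries. Its values were 5.32 for TraesCS2D02G107800, 5.07 for TraesCS7A02G034500, -4.96 for TraesCS6A02G023300 and -4.96 for TraesCS5A02G219300. Without drought, the same interaction was called in 7888 genes, in 1 of 100 splits of the 12 libraries, with 5068 in the highest other, and in 1 of 100 permutations, with 1324. There it was 6.93 for TraesCS3B02G010200, a control-only gene whose value comes from the controls, 6.33 for TraesCS5A02G257700, -4.31 for TraesCS5D02G227500 and -4.25 for TraesCS5A02G219300. The interaction of all 3 treatments was called in 17272 genes as deposited. As many were called in 1 of 100 splits, with 11 in the highest other, and in 1 of 100 permutations, with 2886. Both used deposited values, so neither separates this interaction from the shift of the 6 libraries. Rescaled, the interaction was called in 9706 genes. It was 6.60 for TraesCS1B02G449300, 6.27 for TraesCS1B02G449400, -8.30 for TraesCS5D02G042300 and -7.47 for TraesCS7D02G014300; the last 2 genes were listed at 0 in control, so these values depend on the pseudocount. The drought effect under CO2+temperature minus that alone was called in 5844 genes. As many were called in 2 of 100 splits of the 12 libraries, and the other split called 7863, more than the real one. Such splits also move the effects of the single treatments between the compared groups. The count in them therefore cannot tell whether chance gives so many genes. With the residuals permuted, 1 of 100 orders called as many, and the highest other called 1. The values were 6.88 for TraesCS3B02G010200 and 4.83 for TraesCS1B02G401400, both control-only genes whose values come from the controls, -5.18 for TraesCS6B02G412100 and -4.66 for TraesCS3D02G219800. The last call was lost without CO2+temperature replicate 2 (value -4.45, limma, Benjamini-Hochberg adjusted p = 0.057).

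The lower median-ratio factors of the 6 temperature+drought and CO2+drought libraries enter the temperature by CO2 and 3-way interactions directly. A few abundant genes taking more of the FPKM would need the share of the top 100 genes to be 12.9 percentage points higher in the 6, and it was higher by 1.14. The CO2+temperature+drought libraries had log2 factors of 0.0649 to 0.0716, against 0.0521 to 0.0919 in the 15 other libraries outside the 6. Those of the 6 were at most -0.1571. These values cannot decide whether drought on top of another treatment lowers most genes. If the 18 had been scaled to one another, they would have like factors whatever drought did. A candidate explanation is that the 2 sets of libraries were scaled separately: the 6 columns were the 6 written to 9 decimals, with none of the other 18 so written. A change of most genes in these 2 groups stays open, because the set and the groups coincide.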

How the results depend on the processing

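The fit to the 18 libraries, the fit without drought replicate 2 and CO2+temperature replicate 1, the fit without the genes present in control libraries alone, and all alternatives of the 3 added contrasts were chosen after the data were seen. Every total of called genes stayed within 1.5 times of its value with a pseudocount of 0.1 and with no filter on low values, although the falls under drought went from 378 to 720 with no filter. Of the totals, rescaling moved that of the 3-way interaction by over 1.5 times, from 17272 to 9706 genes. By direction it moved more: falls went from 17132 to 9877 in temperature+drought, from 16654 to 9202 in CO2+drought and from 16544 to 9029 for CO2 added to drought. Rises for CO2 added to temperature+drought went from 15934 to 6893, positive temperature by CO2 interactions from 17127 to 9824 and positive 3-way interactions from 14304 to 4190. Library quality weights, whose estimation did not converge fully, raised the counts to 5792 for drought, 19020 for temperature, 20967 for CO2+temperature and 28308 for CO2+temperature+drought against control. They gave 33608 for CO2 added to drought, 18215 added to temperature, 42899 added to both and 27658 for drought added to CO2+temperature. The interactions rose to 25784 (drought by temperature), 21840 (drought by CO2), 30807 (3-way), 19591 (temperature by CO2 without drought) and 18904 (drought under CO2+temperature minus alone). The cause was not tested. Fits to only the 6 libraries compared gave 1652 genes for drought, 8291 for CO2 added to temperature+drought and 6872 for drought added to CO2+temperature. In these fits CO2 alone called 20961 genes, more than temperature+drought at 18953, and all 3 treatments called 9779. The main fit shares 1 variance per gene over the 8 groups, whose root mean square SD ranged from 0.141 (CO2) to 0.305 (CO2+temperature+drought). Its p-values can be too small for groups of larger spread and too large for those of smaller spread. In fits to only the libraries compared, more genes were called for CO2 (16011 to 20961), CO2+temperature (12971 to 16313) and drought (866 to 1652). These treated groups had the smallest spread. Fewer were called for those of largest spread, temperature+drought (24046 to 18953) and all 3 treatments (13610 to 9779). CO2+drought (23383 to 23980) and temperature (7525 to 7275) moved less. Such fits also rest on fewer libraries, so unequal spread was not tested by itself. For drought against control, the fit to the 18 libraries called 1449 genes, and that without drought replicate 2 and CO2+temperature replicate 1 called 425, with fewer libraries. Leaving out each library gave 392 to 1008 genes for drought, with 392 without control replicate 1, 562 without control replicate 2, 416 without drought replicate 1 and 420 without drought replicate 2; no other total moved by over 1.5 times. Without the genes present in control libraries alone, drought called 750. The replicate numbers did not pair the libraries: 12 of 84 same-numbered pairs correlated over 0.1 (from -0.285 to 0.438), and 11 of 24 libraries correlated best with their own number. With the replicate block, drought called 991 genes and temperature 7630, and no count moved by over 1.5 times. The 68 named results were checked only with a pseudocount of 0.1, rescaled libraries, the replicate block and each library left out in turn. Of these 948 alternatives, 944 kept their direction and call, 4 lost the call and 0 reversed. The genes were picked for the largest changes among called genes, so keeping the call was likely from the start. The gene list alternatives were not run, since 0 of 31 lists held a matched gene. Absolute depth was unknown, which limits what can be said of genes at low FPKM.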

Other observations

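The tests in this part were chosen after the results they bear on were seen. Genes that changed by at least 1 on the log2 scale in the same direction lay side by side more often than chance in some groups. With runs of at least 5 neighbouring tested genes on rescaled values, temperature+drought had 15 runs against control (5 higher, 10 lower), where 200 shuffles of the calls within chromosomes gave a mean of 0.07 and at most 1 (permutation p = 0.005, the smallest these shuffles can give). CO2+drought had 13 runs, CO2+temperature+drought 6, CO2+temperature 3 and CO2 alone 2, each with the same p, and drought and temperature alone had 0. A run on chromosome 3B from TraesCS3B02G130500 to TraesCS3B02G131300 held 6 genes that were higher in CO2+drought, temperature+drought and CO2+temperature+drought, with median log2 changes of 2.45, 2.45 and 2.15, and in CO2+temperature a run of 8 genes from TraesCS3B02G130300 spanned it (median 2.23). A run of 5 genes on chromosome 2B, from TraesCS2B02G445100 to TraesCS2B02G445600, was lower in the 5 groups with CO2 or with temperature+drought, with median log2 changes of -2.06 in CO2, -1.41 in temperature+drought, -2.19 in CO2+drought, -1.67 in CO2+temperature and -2.63 in CO2+temperature+drought. These groups share their controls, so the runs are not independent between groups. Neighbouring gene copies can share fragments, so a run need not be as many separate changes.

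In the control libraries, 96 genes stood at 0.5 FPKM or more in all 3 replicates and at 0.15 of the lowest control or less in all 21 other libraries, with a median control level of 2.17 FPKM. By the same rule 38 genes were present and 5 absent in temperature+drought alone, 4 were present in CO2+temperature alone, and 0 were found in the 5 other groups. Of the 96, 21 lay on chromosome 6B (odds ratio 6.67; Fisher's exact test, adjusted p = 4.8e-09 over 21 chromosomes), 11 on 7A (odds ratio 2.57, adjusted p = 0.046), 0 on 5D (adjusted p = 0.046), and 16 on the D subgenome (odds ratio 0.391, Fisher's exact p = 0.00022). Genes on a chromosome are not independent, so these p-values can be too small. Control libraries wholly from another genotype would also lack genes found in the rest, and 0 genes were absent from control alone. The rule for absence asked for 0.5 FPKM or more in all 21 other libraries, over 7 treated groups, against 3 libraries for presence. The 2 counts are thus not on an equal footing, and the 0 does not exclude another genotype. RNA of a second genotype mixed into the control libraries may account for the 96 genes, since a mixture adds genes and removes none, but the sets of temperature+drought and CO2+temperature also lean to genes present, so this lean alone does not mark a mixture. That every treatment switches off the same genes cannot be told apart from a difference of the control plants, because the 7 treated groups share those controls. All 72 that were tested were called lower in each treated group, but the rule that picked them set this direction in advance.

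The summed FPKM of the first 17 genes of chromosome 1A, TraesCS1A02G000100 to TraesCS1A02G001700, ran from 9.956 to 17 in the 6 temperature+drought and CO2+drought libraries, was 19.22 in drought replicate 2 and 9.07 in CO2+temperature replicate 1, and had a median of 3.281 over the 18 libraries of the other set. Separate scaling of the 6 libraries, a fold of 1.18 that lowers their values, cannot give the 4.06-fold higher level. A rise under drought combined with another treatment is argued against by CO2+temperature+drought, at 0.931 of the control level, and by drought replicate 2, at 4.91 times the other drought replicates. Ribosomal RNA reads in these libraries could give such a block, as 39 of the first 40 genes annotated on chromosome 1A in the reference are ribosomal RNA genes, but this cannot be told apart from other causes, because none of the 17 identifiers matched the reference.

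For contrasts of 3 libraries against 3, the 10 splits cannot give a share under 0.1, so they are too few to exclude chance; the real split alone (1 of 10) called as many genes in each. The real and highest other counts were 866 and 0 for drought, 7525 and 1 for temperature, 16011 and 0 for CO2, 24046 and 739 for temperature+drought, and 23383 and 0 for CO2+drought. They were 12971 and 0 for CO2+temperature and 13610 and 43 for all 3 treatments. For CO2 added to drought they were 22284 and 3, to temperature 6216 and 1, and to temperature+drought 20950 and 2573. For drought added to CO2+temperature they were 10439 and 12.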
